A study of Mus musculus with 23 samples.

How the data were processed

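Neurons were dissociated from micro-dissected arcuate hypothalamus with papain, and GFP-positive cells were sorted by hand into single tubes, per the labels' protocols. Polyadenylated RNA of each cell was amplified with the SmartSeq2 method, and libraries were made with the NuGen Ovation Rapid kit, per the labels' protocols. Reads were processed with CASAVA 1.8, TopHat and Cufflinks on mm10, per the submitters' processing notes; the versions of TopHat and Cufflinks, the annotation and the filters are not given in the sources used here. The authors deposited 1 table of FPKM values per gene and cell. FPKM divides the fragments of a gene by its length in kilobases and by the mapped fragments of the library. This makes genes of different length comparable but inflates very short RNAs, and a few very abundant peptide transcripts lower every other value in a cell. SmartSeq2 libraries carry no molecular identifiers, so amplified copies are counted as reads.

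The deposited table had 23896 rows. A block of 12 rows in it held leftover spreadsheet summaries with negative or empty cells and no gene, and was left out. No other value was below 0. Of the remaining 23884 rows, 286 were identical copies and were dropped, 27 had gene names turned into dates by a spreadsheet and were kept apart without a name, and rows of the 124 symbols that still had several rows were summed, which gave 23400 genes. Hba-a1 and Hba-a2, like Hbb-b1 and Hbb-b2, are near-identical copies, so the split of reads within each pair is uncertain. The loci listed for each pair also overlap, starting at 32296489 and 32296492 on chromosome 11 and at 103812528 and 103812524 on chromosome 7. Their cell counts therefore do not describe separate genes. The table has 0 genes on the mitochondrial chromosome. Locus starts were taken to count from 0, because for 9298 of 21591 genes compared with RefSeq the start was 1 lower and the end equal, against 263 with both equal. Coordinates are given from 1, on mm10, with strand and gene type from GENCODE.

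FPKM sums per cell ran from 379513 to 687511. Low values of a gene lie on steps worth 1 read each, so the most frequent ratio of low values (under 0.5 FPKM, loci of at least 500 bp, log2 bins of 0.02) between a cell and cell 12 gives their relative depth. No absolute depth was derived. This estimate recovered known relative depths within 1% on simulated data of 15000 genes.

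All results are descriptions: each sample is 1 cell, cells are not replicates, and the labels do not tie cells to the 2 mice, so no test between cells and no p-value was computed. A cell was counted for a gene at or above 1 FPKM. Shares of cells are given with exact Clopper-Pearson 95% intervals, which cover counting error only. Log values are log2(FPKM + 1). Clustering used Ward linkage on the 1000 genes with the highest variance among those at or above 1 FPKM in at least 3 cells; it recovered 4 simulated groups with an adjusted Rand index of 1. Doublets were not called, since each tube received a hand-picked cell. An exact 0 is described as listed at 0.

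Gene lists, markers, comparisons and alternatives were fixed before the data were examined. Named genes are the 17 core genes and, in each of 30 lists, up to 4 more members, or 8 in the receptor and the peptide list. These members were the ones that reached 1 FPKM in the largest numbers of cells, however few. Also named are the 20 genes with the highest SD of log2 values among those at 1 FPKM in 3 to 20 cells. For the title prefixes, up to 10 genes per direction with the largest difference of means are named. Of the list genes, Drd1, Hbb-bs, Hbb-bt and Scn2a were not analysed here under those symbols, and some genes that the rule selects are not reported here. Alternatives were other thresholds, rescaling each cell to 1000000, each title set alone and, for clusters, another pseudocount, filter, gene number, cluster number and linkage.

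A carry-over index was added after the data were seen. It uses genes with a highest value of at least 100 FPKM, no more than 2 cells at or above 10% of that value, those cells in 1 title set, and a locus of at least 500 bp. For each such gene the value in every other cell of the set was divided by the set's sum, and the index is the median over genes, in percent. On simulated data of 23400 genes with known carry-over within sets, the index was between 0.881 and 0.933 of the known share. In simulated data without carry-over, 1 of 33 such genes was higher in its own set and 0 in the other set. The simulations thus held little low expression of the cells' own that differed between sets. In the real data such expression could raise the index. The recovery therefore does not show that the index measures carry-over alone there. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.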

Results

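The series holds 23 single-cell RNA-seq libraries, each made from 1 neuron of the mouse arcuate hypothalamus. The arcuate nucleus lies at the base of the hypothalamus and contains neurons that control feeding, reproduction and growth. The cells carried a Cre-dependent GFP fused to a ribosomal protein, switched on by Cre under the gene of the vesicular glutamate transporter VGLUT2, and GFP-positive cells were picked by hand after dissociation. The labels give 2 male mice as donors and do not say which mouse a cell came from, so the 23 cells form 1 group without biological replicates. Cells are numbered 1 to 23 in the order of their records. Titles of cells 1 to 15 share the prefix JCb5.2 (set 1, 15 cells) and those of cells 16 to 23 the prefix JCb6 (set 2, 8 cells); the labels do not explain the prefixes. The study used these profiles to look for receptors that mark excitatory arcuate neurons.

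Each cell yielded a broad transcriptome. At or above 1 FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), the median cell had 7090 genes, with a range from 4054 in cell 17 to 8042 in cell 13. The median was 7131 genes in set 1 and 6608.5 in set 2. In all, 14897 of 23400 genes reached 1 FPKM in at least 1 cell and 1685 did so in every cell. Housekeeping transcripts were present throughout: Ppia had a median of 2523 FPKM (range 1563 to 3989), Eef1a1 665 FPKM, Actb 624 FPKM and Hprt 399 FPKM, and 7 of the 8 genes of this list reached 1 FPKM in all 23 cells. Rpl10a, the gene of the ribosomal protein in the reporter fusion, had a median of 448 FPKM (181 to 861). Relative depth, read from the spacing of low values, differed between libraries by up to 4.17-fold, with cell 14 the shallowest and cell 20 the deepest. Absolute read numbers were not used here.

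**Figure D1:**
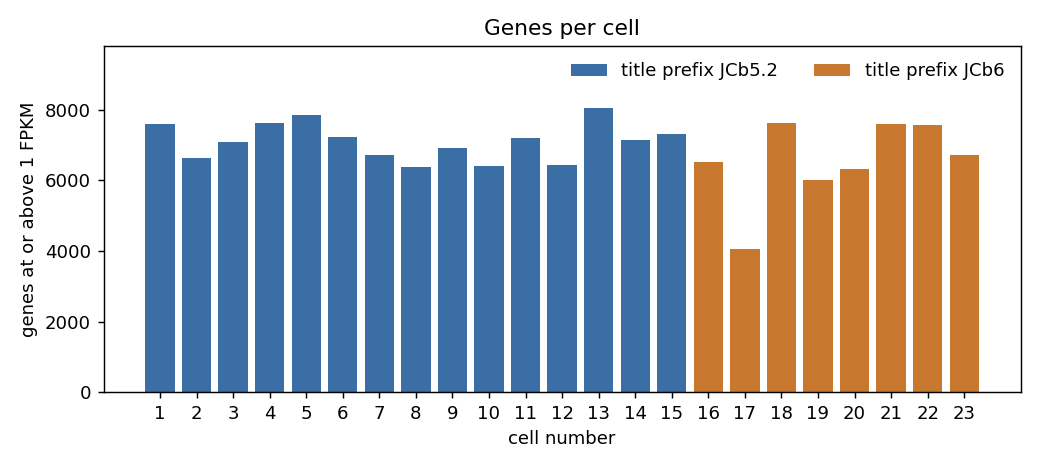
Number of genes at or above 1 FPKM (vertical axis) in each of the 23 cells (horizontal axis, cell number), 1 bar per cell and coloured by title prefix. Bars run from 4054 genes in cell 17 to 8042 in cell 13, with a median of 7090.

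The cells had the transcripts of neurons and few of glia or vessels. Of 12 pan-neuronal genes, 10 reached 1 FPKM in 12 or more cells and 7 in all 23. Uchl1, a neuronal ubiquitin hydrolase, had a median of 643 FPKM (363 to 1406), the microtubule regulator Stmn2 308 FPKM (54.4 to 943), and the neuronal long non-coding RNAs Meg3 and Snhg11 307 and 272 FPKM. Snap25, part of the synaptic vesicle fusion machinery, reached 1 FPKM in all 23 cells with a median of 17 FPKM, while the vesicle calcium sensor Syt1 did so in 8 cells. No astrocyte or oligodendrocyte gene reached 1 FPKM in 12 or more cells. Among the 7 astrocyte genes, 5 reached it in no cell; the exceptions were Slc1a2 in 4 cells and Gfap in 3, with 165 FPKM of Gfap in cell 12. Among the 7 oligodendrocyte genes, Mbp was at 1 FPKM in 10 cells (highest 41.3 FPKM), Mag in 5 and Cldn11 in 3.

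The other non-neuronal lists differed. Of the 3 oligodendrocyte precursor genes, Cspg4 and Gpr17 reached 1 FPKM in 1 cell each. Of 7 microglial genes, Csf1r did so in 3 cells and P2ry12 and Aif1 in 1 each. Of 6 endothelial genes, Pecam1 did so in 5 cells and Ly6c1 in 1, and of 5 mural and meningeal genes, Pdgfrb in 4 cells and Rgs5 in 1. The tanycyte list had 4 of 5 genes in at least 1 cell, led by the intermediate filament Vim in 14 cells (highest 258 FPKM, cell 12), and including Frzb in 4 and Col23a1 in 1. The ependymal list had Foxj1 in 11 cells and Rarres2 in 6, and the pituitary list had Gh in 1 cell at 1.50 FPKM. Red blood cell transcripts were common: Hba-a2 reached 1 FPKM in 22 cells (median 105 FPKM, highest 1594 in cell 19), Hbb-b2 in 12, Hba-a1 in 10 and Hbb-b1 in 8. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d reached 1 FPKM in 18, 11, 10 and 8 cells, and Xist, which silences the inactive X in females, in 5 cells (highest 5.26 FPKM). Cell 23 had 2.69 FPKM of Xist and at most 0.143 FPKM of any of the 4 Y-linked genes.

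The transcript of the Cre driver gene was found in nearly every cell. Slc17a6, which encodes VGLUT2 (chromosome 7, 51621830 to 51671126 in mm10, plus strand, protein coding), reached 1 FPKM in 22 of 23 cells, 95.7% (exact Clopper-Pearson 95% interval 78.1 to 99.9%), with a median of 32.1 FPKM. The exception was cell 11 at 0.520 FPKM, and values were also low in cells 22 (1.65 FPKM), 15 (4.47), 21 (5.04) and 17 (7.02). The highest value was 139 FPKM in cell 18. The other vesicular glutamate transporters were scarcely detected: Slc17a7 reached 1 FPKM in no cell (interval 0 to 14.8%) and Slc17a8 in 2, with at most 1.92 FPKM. Intervals here cover counting of cells only, since amplified reads without molecular identifiers are not independent molecules and 2 mice stand behind all cells.

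Most of these cells also had transcripts of GABA synthesis, but few had the vesicular GABA transporter. Gad1 and Gad2, the glutamate decarboxylases that make GABA, reached 1 FPKM in 15 cells (65.2%, interval 42.7 to 83.6%) and 16 cells (69.6%, 47.1 to 86.8%), with highest values of 247 FPKM in cell 15 and 130.4 FPKM in cell 13. Slc32a1, which loads GABA into vesicles, reached 1 FPKM in 2 cells (8.70%, 1.07 to 28.0%), cell 15 at 15.3 FPKM and cell 5 at 2.81 FPKM, and was listed at 0 in 16 cells. Slc17a6 together with at least 1 of Slc32a1, Gad1 and Gad2 was found in 18 of 23 cells, 78.3% (56.3 to 92.5%). At 10 FPKM the joint count was 11 cells, 47.8%, so it depends on the threshold. Of 8 genes of other transmitter phenotypes, 5 reached 1 FPKM in no cell; Dbh and Tph2 did so in 3 cells each and Chat in 2, with no value above 20.5 FPKM.

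Oxtr, the oxytocin receptor gene (chromosome 6, 112473684 to 112489808, minus strand, protein coding), was found in a minority of cells. It reached 1 FPKM in 5 of 23 cells, 21.7% (interval 7.46 to 43.7%): cell 13 at 22.8 FPKM, cell 6 at 12.2, cell 7 at 7.67, cell 4 at 7.46 and cell 2 at 6.09. All 5 belong to set 1, where the share was 33.3% (11.8 to 61.6%). In set 2 the gene was listed at 0 in each of the 8 cells, which leaves a share of up to 36.9%. The intervals of both sets overlap at 1 FPKM, and no test between the sets was made. Counting any value above 0, Oxtr was listed in 14 of the 15 cells of set 1, all but cell 15, and in 0 of the 8 of set 2. The set 1 values under 1 FPKM were highest in cell 12 (0.360 FPKM) and cell 14 (0.263 FPKM). These cells had the highest carry-over index of set 1, 0.689% and 0.489%. Reads carried over within the set could give such values, so they do not show wider expression of Oxtr. Each Oxtr cell also had Slc17a6. Mc4r, the melanocortin 4 receptor gene (chromosome 18, 66857705 to 66860487), reached 1 FPKM in 3 cells, 13.0% (2.78 to 33.6%), with 50 FPKM in cell 2, 20 in cell 9 and 2.36 in cell 21. Cell 2 was the 1 cell with both receptors. In set 2, Mc4r was above 0 in all 8 cells (0.227 to 2.36 FPKM) and highest in cells 21 and 17. Oxt and Avp were highest in the same cells, so a shared source, as discussed below for them, is not excluded for cell 21.

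Other feeding and hormone receptors were mostly found in a minority of cells. Of 43 measured receptor genes, 37 reached 1 FPKM in at least 1 cell, 10 in 12 or more and 6 in none. Frequent ones included the BDNF receptor Ntrk2 (21 cells, median 18.4 FPKM), the neuropeptide Y receptor Npy1r (19 cells, 8.71 FPKM), the PACAP receptor Adcyap1r1 (19 cells, 6.42 FPKM), the glucocorticoid receptor Nr3c1 (15 cells, 6.34 FPKM), Mc3r (15 cells, 3.09 FPKM), Sstr1 (14 cells, 8.25 FPKM) and the orexin receptor Hcrtr2 (13 cells, 1.48 FPKM). Of 15 measured ion channel genes, 15 reached 1 FPKM in at least 1 cell and 7 in 12 or more, among them Scn2a1 (22 cells, median 10.9 FPKM), Cacna1g (15 cells, 4.47 FPKM) and Scn9a (15 cells, 1.29 FPKM).

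Transcripts of classical arcuate types were present in every cell at 1 FPKM, at levels that differed widely. All 23 cells (100%, interval 85.2 to 100%) had at least 1 of Pomc, Agrp, Kiss1, Th, Ghrh and Sst. Pomc, the precursor of the satiety peptide alpha-MSH, ranged from 25.5 FPKM in cell 2 to 9534 FPKM in cell 12, and exceeded 1000 FPKM in 8 cells (4, 5, 6, 11, 12, 13, 21 and 22). Cartpt ranged from 50.3 FPKM in cell 20 to 32793 FPKM in cell 4, with 15794 to 32793 FPKM in cells 4, 6, 12 and 13. Pomc, Agrp and Kiss1 were above 0 in all 23 cells, while Ghrh was above 0 in 11. At 1 FPKM, Pomc passed in all 23 cells, Sst in all 15 of set 1 and Kiss1 in all 8 of set 2. The lower of these values may be reads carried over between libraries of a set, so the share of 100% may overstate expression. Pomc differed between the sets in this. In set 2 it was 25.6, 39.0, 40.5 and 54.2 FPKM in cells 20, 19, 23 and 18. Their carry-over indices of 0.0751, 0.152, 0.225 and 0.179% of the set's sum would give less, which argues against carry-over alone there. In set 1 the lowest value, in cell 2, was at a level that its index of 0.147% could give. When a value had also to reach 5% of the gene's highest value in its set, a condition chosen after the data were seen, 18 cells (78.3%) had a classical gene and Pomc was counted in 11. The condition is strict, since it also dropped cell 7 at 412 FPKM of Pomc.

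High values of the other type genes fell in few cells. Kiss1, which encodes the kisspeptin precursor, stood at 895 to 2963 FPKM in cells 8, 17, 19, 20 and 23 and at or below 62.5 FPKM in the other 18. In cells 8, 17, 19 and 20, Tac2 (neurokinin B) was at 1206 to 1814 FPKM, and Pdyn (dynorphin) at 128 to 1029 FPKM; cell 23 had 67.0 FPKM of Tac2 and 1117 FPKM of Pdyn. Pdyn itself reached 1 FPKM in all 23 cells. Npy, the appetite-stimulating neuropeptide Y, was at 2539 FPKM in cell 10 and 2659.6 FPKM in cell 15, where Agrp was at 39.7 and 433 FPKM. Sst (somatostatin) was at 29792 FPKM in cell 15, 4394 in cell 14, 1342 in cell 9 and 903 in cell 2. Lower values of these genes were spread over many cells, so the count depended on the threshold. Carry-over between libraries of a title set may account for some of them. At 1 FPKM, Kiss1 was counted in 20 cells (87.0%, interval 66.4 to 97.2%), Npy in 15 and Sst in 15 (65.2% each, 42.7 to 83.6%), Tac2 in 11 (47.8%, 26.8 to 69.4%) and Agrp in 9 (39.1%, 19.7 to 61.5%). When a value had also to reach 5% of the highest in its set, the counts were 5, 2, 2, 4 and 4. For Agrp these were cells 10 and 15 of set 1 and cells 17 and 21 of set 2. The latter passed at 2.93 and 3.63 FPKM because no cell of set 2 was higher, so the condition says little about them. Th, needed for dopamine synthesis, reached 1 FPKM in 2 cells (8.70%, interval 1.07 to 28.0%), with a highest value of 9.08 FPKM. Ghrh did so in 1 cell (4.35%, 0.110 to 21.9%), at 3.67 FPKM. Th was listed at 0 in all 15 cells of set 1 and above 0 in all 8 of set 2. It was highest in cells 21 and 17, as were Oxt and Avp, so a source shared with them is not excluded.

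**Figure D2:**
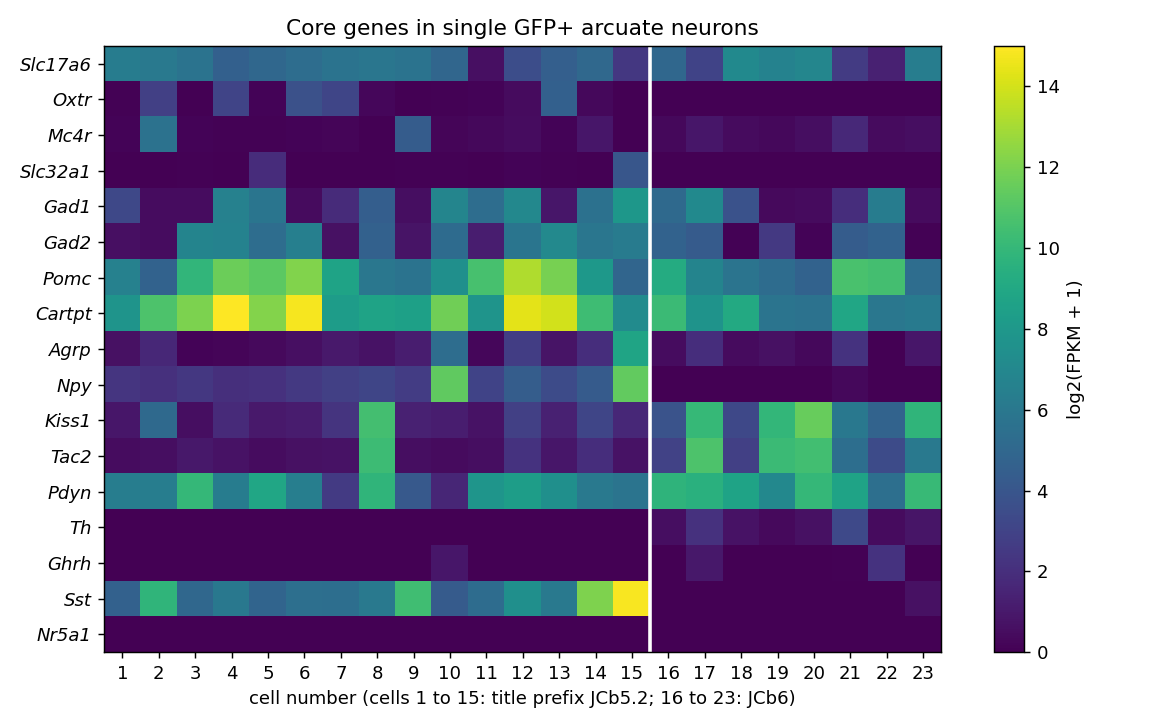
Heat map of log2(FPKM + 1) of 17 core genes (rows) in the 23 cells (columns), with a white line between the 2 title prefixes. Cartpt and Pomc are brightest in cells 4, 6, 12 and 13, Kiss1 and Tac2 in cells 8, 17, 19 and 20, and Oxtr shows in cells 2, 4, 6, 7 and 13.

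Further markers of these types were less uniform. In the POMC list, the repressor Tbx3 reached 1 FPKM in 22 cells (median 33.8 FPKM), the prohormone convertase Pcsk1 in 18, Nhlh2 in 13 and Prdm12 in 9. In the AgRP list, Otp was found in cells 10 and 15 alone (62.6 and 17.8 FPKM), Acvr1c in 7 cells and Corin in 2. In the KNDy list, named for kisspeptin, neurokinin B and dynorphin, Pgr was found in 14 cells, Esr1 in 10, Tacr3 in 5 and Nr5a2 in 5. The dopamine list had Slc18a2 in 16 cells, Ddc in 12, Gch1 in 11 and the dopamine transporter Slc6a3 in no cell. In the GHRH list, Gal reached 1 FPKM in 23 cells (median 182 FPKM, highest 3279 in cell 6) and Gsx1 was listed at 0 throughout. Nr5a1, the defining gene of the neighbouring ventromedial nucleus, was listed at 0 in all 23 cells. Of its list, Adcyap1 was found in 9 cells, Sox14 in 7, Bdnf in 5 and Fezf1 in 1 (cell 9, 60.5 FPKM). Cell 9 had the other 3 as well, with 44.6 FPKM of Bdnf, 26.7 of Sox14 and 7.25 of Adcyap1.

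Some arcuate and hypothalamic transcription factors were found in most cells and others in none. Of 17 such genes, 11 reached 1 FPKM in at least 1 cell, 6 in 12 or more and 6 in no cell. Nkx2-1 did so in 22 cells (median 44.6 FPKM), Tbx3 in 22, Isl1 in 20 (20.5 FPKM) and Bsx in 14 (2.01 FPKM). Of 40 neuropeptide and secretory genes, 29 reached 1 FPKM in at least 1 cell and 8 in all 23. Secretory genes were found throughout at varying levels: Cpe had a median of 397 FPKM (10.7 to 719), Scg2 299 (96.5 to 920.1), Chgb 162 (10.7 to 335) and Chga 83.7 (3.17 to 224), each in all 23 cells, and Pcsk2 was found in 19 cells at 25.1 FPKM. Immediate-early genes, which rise within minutes of activity or of tissue dissociation, were high: 7 of 16 reached 1 FPKM in all cells. Fos had a median of 524 FPKM (11.2 in cell 16 and 25.0 in cell 9 to 2469 in cell 10), Junb 229.6 FPKM, Egr1 213 FPKM and Jun 212 FPKM.

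The title prefixes differed in a few peptide genes. Oxt and Avp, the oxytocin and vasopressin genes of magnocellular neurons outside the arcuate nucleus, were present in all 8 cells of set 2, at 322 to 3014 FPKM and 571 to 5186 FPKM. In set 1, Oxt reached 1 FPKM in 3 of 15 cells (at most 30.8 FPKM) and Avp in 4 (at most 2.01 FPKM). Sst and Npy were the reverse: all 15 cells of set 1 had at least 18.6 FPKM of Sst and 3.06 FPKM of Npy, and no cell of set 2 had more than 0.608 and 0.243 FPKM. Beyond Oxt and Avp, the list of other hypothalamic nuclei had Hcrt in 2 cells and Hdc, Sim1 and Nms in 1 each. Mean log2(FPKM + 1) of Sst was 7.19 in set 1 and 0.09 in set 2, of Npy 3.99 and 0.04, of Sncg 5.43 and 0.72, and of Cartpt 10.91 and 7.44. The other 6 genes among the 10 with the largest excess in set 1 were Hexa, Bax, Tomm5, Snx7, Asb4 and Ifi27l1. In the other direction, means were 0.35 and 10.01 for Avp, 0.93 and 9.19 for Oxt, 1.48 and 6.53 for Tac2 and 2.37 and 7.40 for Kiss1, followed by Mir3064, Snora41, Snord35a, Snora65, Nell1 and 2700097O09Rik. Low values shared within a set, as of Sst, Npy, Kiss1 and Tac2, may be carried-over reads. With 1 group and no test, none of these genes is called changed.

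**Figure D3:**
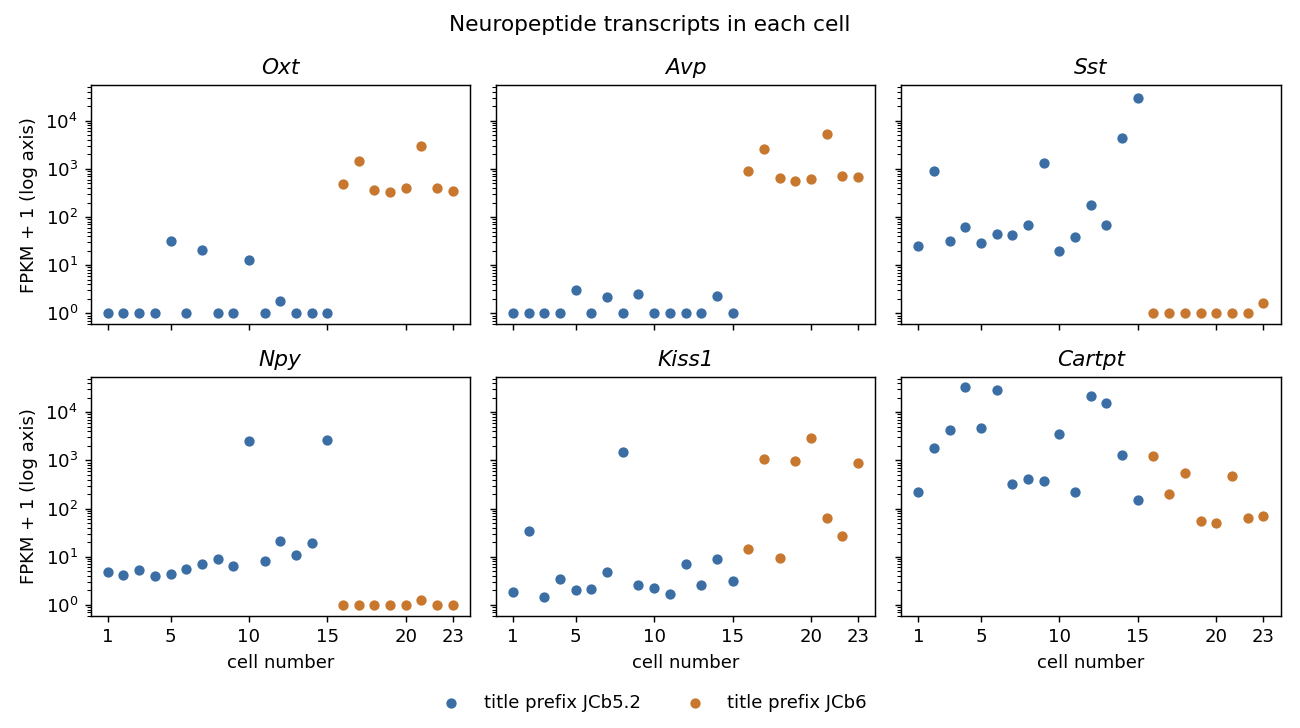
FPKM + 1 on a log axis (vertical) of 6 peptide genes in each of the 23 cells (horizontal axis, cell number), 1 point per cell and coloured by title prefix. Oxt and Avp exceed 300 FPKM in the 8 cells of set 2 alone, Sst and Npy have a floor in the 15 cells of set 1, and Kiss1 and Cartpt span high and low cells.

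Cells were grouped by hierarchical clustering, with short loci included. The leading genes of each cluster were ranked after loci under 300 bp were left out. Cutting the tree into 4 clusters gave cells 4, 6, 12 and 13, with Sncg, Cartpt and Pomc as leading genes; cells 17 and 19, with Tac2, Kiss1 and also Avp, which was high in every cell of set 2; cells 8, 20 and 23, with Kiss1 and Tac2; and the remaining 14 cells, with Gstm6, Hebp1 and Gpr101. The adjusted Rand index of these clusters against the prefixes, where 1 is identity and 0 is chance, was 0.0924. Other settings gave values up to 0.323, so its size depends on the settings. The 20 genes that varied most between cells were dominated by short RNAs, whose FPKM is inflated by the division by length: 18 had a locus shorter than 300 bp. AF357425 led with an SD of 5.61 on the log2 scale, followed by Snord49b, Mir1982, Mir3064, AF357355, Snord55, Mir344g, Mir3082, Mir1896, Mir539, Mir882, Mir1892, Mir130a, Gm12238, Snord57, Snord65, Mir5133 and Mir5126. The 2 longer genes were Avp (SD 4.77) and Oxt (SD 4.32).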

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

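The limits on cells counted at a share of the set's highest value, on cells with a high carry-over index and on short loci were chosen after the data were seen; the other alternatives were planned. With any value above 0 counted, shares became 100% for Slc17a6 and 100% for Slc17a6 with a GABA gene, and the median cell had 11975 genes. The values that these shares added were under 1 FPKM, such as Slc17a6 at 0.520 FPKM in cell 11. Carry-over within a set is not excluded for such values, so they do not show wider expression. The share of Oxtr became 60.9% (14 of 15 cells of set 1 and 0 of 8 of set 2). Its values under 1 FPKM were at a level that carry-over within set 1 could give. At 10 FPKM the joint share was 47.8% and the median cell had 4252 genes. Rescaled to a sum of 1000000 per cell, Slc17a6 was in 100% of cells, because the low value of cell 11 named above passed the threshold. Set 2 alone gave 100% for Slc17a6 and 0% for Oxtr. At 5% of the set's highest value, a classical arcuate gene was left in 78.3% of cells. The adjusted Rand index moved from 0.0924 to 0.323 with a pseudocount of 0.1, 0.213 with 2000 genes, 0.264 with 3 clusters, 0.213 with average linkage, 0.296 after rescaling, 0.173 without cells 12, 14 and 21, which had an index above 0.4%, and 0.235 without loci under 300 bp. Leaving out 1 cell at a time gave 0.0331 to 0.269. The cause was not tested. The remaining alternatives stayed within the interval or spread of the main value, but the interval covers counting error only and is wide. Among them, Oxtr fell to 2 of 23 cells (8.70%) and Slc17a6 to 18 (78.3%) at 10 FPKM.

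Among the shares of 106 other named genes, 67 rose beyond their interval with any value above 0, 49 fell at 10 FPKM, and 3 rose after rescaling. In set 1 alone 5 rose and 9 fell, and in set 2 alone 11 rose and 17 fell; 6 fell at 1% and 12 at 5% of the set's highest value, and leaving out cells 12, 14 and 21 moved 0. Removing mitochondrial genes was not run because the table has 0 of them, and leaving out cells with fewer than 2000 genes would remove no cell. Depth limits absence: a gene listed at 0 in a single cell is not shown to be absent from it.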

Other observations

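All tests in this part, and the pairing of Oxtr with Cckar, were chosen after the values were seen. Cckar, the gene of the receptor for the satiety hormone cholecystokinin, was at or above 10 FPKM in 8 of 23 cells: 2, 4, 5, 6, 7, 11, 13 and 22. All 5 cells with Oxtr were among them, where 1.74 would fall if the genes were placed independently over all cells, and 2.33 within set 1, which holds all 5 Oxtr cells and 7 of the 8 Cckar cells. With Cckar also counted at 1 FPKM, in 12 cells, 11 of them in set 1, the expected numbers were 2.61 and 3.67. Cckar was at 125 FPKM in cell 6, 68.1 in cell 13, 28.7 in cell 2, 22.9 in cell 4 and 16.9 in cell 7. This is 1 of 52 receptor and peptide genes set beside Oxtr, without a test, and 4 of the 5 cells also had over 400 FPKM of Pomc.

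Low values of genes with a clear source cell followed the title sets: of 33 genes with 1 or 2 high cells, 28 had a higher median in the other cells of the source's own set than in the other set, 1 had a lower one and 4 were equal, so 96.6% of the unequal pairs went the way that reads carried over between libraries of 1 set would give. Cell 17 was the source of 16 of them. Without that library 17 genes were left, 13 higher in their own set, 0 lower and 4 equal. Sst and Npy are themselves among the 28, so their own floors are part of that count and not explained by it independently. Against carry-over, 1 of the equal genes, the ribosomal RNA precursor Rn45s, was at 32981 FPKM in cell 22 and listed at 0 in the other 22 cells, although every cell uses it and such a 0 can be a failed estimate. The number of the 14 astrocyte and oligodendrocyte genes at 1 FPKM in 12 or more cells was 0, which goes against free RNA of the tissue, but the red blood cell gene Hba-a2 was at 1 FPKM in 22 cells, which goes with it. Carry-over may underlie the floor of Sst and Npy in set 1, with free RNA left open. The same holds for the lowest Kiss1 and Tac2 values of set 2, 8.54 and 6.23 FPKM in cell 18. No biological explanation was tested.

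Oxt and Avp in all 8 cells of set 2 are harder to place. Avp was 1.55 to 1.91 times Oxt while Avp itself spanned 9.09-fold, an SD of log2(Avp/Oxt) of 0.0880, as 1 shared source would give; without cell 21 the Avp span was 4.47-fold and the SD 0.0936, and without cells 17 and 21 they were 1.54-fold and 0.102, so most of the span rests on those 2 cells. Of the 65 other pairs among 12 peptide genes found in all 8 cells, 0% had an SD as low and the lowest was 1.10. That lowest SD was 1.06 without cell 21 and 0.667 without cells 17 and 21. The values argue against Oxt and Avp varying independently of each other. Both genes are neighbours on chromosome 2 (130576173 to 130576988 and 130580677 to 130582541). Joint expression of neighbouring genes by each cell could also keep the ratio steady, so the comparison cannot exclude expression by the cells. No library of the 23 stood out as the source: the highest Avp, in cell 21, was 7.56 times the median of the 8 cells, too little for carry-over at the highest index of 0.741%. A shared source outside the 23 libraries stays open, and the labels do not say whether the prefixes stand for mice, days or runs.

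Gad1 or Gad2 with Slc17a6 and little Slc32a1 was not explained by carry-over from another library of the set. Of the 18 cells, 14 were left when Slc17a6 and at least 1 Gad gene had to reach 5% of the set's highest value. This does not address free RNA of the tissue, a source outside these libraries or more than 1 cell in a tube. Whether Slc32a1 was present and missed cannot be told apart from its absence: 7 cells had only 1 of Gad1 and Gad2 at 1 FPKM, which does not separate a missed transcript from a low level, and Slc32a1 was above 0 in 6 of 19 cells with Gad1 or Gad2. No biological explanation was tested.

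Correlations between cells were slightly higher within the title sets when low values were included. Over genes at 1 FPKM in any cell, the median Spearman correlation was 0.674 within set 1, 0.672 within set 2 and 0.638 between the sets. With values under 1 FPKM set to 0 these became 0.613, 0.568 and 0.580, so the excess within set 1 stayed and that within set 2 did not; removing low values also adds ties. Leaving out loci under 300 bp, the genes that varied most between cells after Avp and Oxt were Sst, Tac2, Kiss1 and Sncg, with SDs of 4.28, 3.72, 3.68 and 3.53 on the log2 scale.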
